A study of Mus musculus with 2 samples.

How the data were processed

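RNA of the pancreas was compared between 2 groups, each measured as 1 pool on 1 array. Per the labels, the groups were set by the diet of the mothers in pregnancy, RNA was extracted with Trizol, and biotin-labelled cRNA was made with a 3' IVT kit for Affymetrix arrays. Such arrays read each gene through 1 or more probe sets near the 3' end of its transcripts. The number of mice per pool, their litters and the time of day of collection are not given in the sources used here.

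The values deposited by the authors are linear intensities per probe set. The program, background correction and scaling behind them are not given in the sources used here. From the values, the mean of each array after trimming 2% of probe sets at each end was 500.003 on both, so both arrays appear to have been set to a common trimmed mean. This removes a difference in total signal, and a real change in total RNA per cell would not be seen. Deposited intensities ranged from 0.685 to 263446 in the control pool and from 0.669 to 266191 in the methionine-deficient pool. No detection calls were used here, so which probe sets lie above background is not known, and differences of dim probe sets depend on the authors' background correction. The number of arrays limits the precision.

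Gene names came from the platform annotation of 2016, updated through gene identifiers to current symbols for 34741 probe sets. Of 45101 probe sets, 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. Probe sets with several symbols or none stayed out of gene counts, and 2897 of these lay past the level filter, of which 197 were at least 2-fold higher and 125 at least 2-fold lower. Genes of the fixed set with no probe set of their own under this annotation were not analysed here, among them Ins1, Mafa, Amy2a5, Mat2a and H19. Gapdh was read only through the array's control probe sets for it. No genome coordinates were used.

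Intensities were taken to log2(value + 1) without further scaling, and the difference is methionine-deficient minus control. This scale slightly understates fold changes of dim genes. The value of a gene was that of its probe set with the highest mean level. A gene was kept if that level reached the median of all probe sets that are not array controls (intensity 150), which left 11848 of 18193 genes. A gene was counted at a 2-fold difference, without a test. The error given is a robust SD for the log2 difference of a single probe set, in 5 bins of probe sets by level. It was estimated from pairs of probe sets of 1 gene, neighbours in level and in the same bin. The difference within each pair was divided by the square root of 2. Across the 4819 genes with at least 2 probe sets past the filter, the log2 differences of the brightest and the second probe set had a Pearson r of 0.028 and a Spearman rho of 0.038, a correlation across genes, which are not independent replicates.

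Before the data were examined, 47 lists of genes were fixed, made up of markers of pancreatic and other cell types and of pathways, and 41 had at least 5 members past the filter. For each, the median log2 difference was placed among 10000 random lists of the same size matched on level in 10 bins, and a list outside the central 95% was counted as outside. The lists for brown adipocyte, erythroid, liver, skeletal muscle and stomach genes and for sex-linked genes had too few members and were given no median. Genes named were also fixed by a rule beforehand: the 15 largest higher and the 15 largest lower differences among genes whose probe sets share a direction, leaving out predicted and unnamed transcripts, up to 4 members of each list with the largest difference, a fixed set of islet, acinar, methylation, stress and reference genes, and the 3' to 5' controls of Actb and Gapdh. Genes named outside this rule are said to have been chosen after their values were seen.

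The counting and the list percentiles were tested on simulated data, in which the noise had the size of the probe-set spread. For the comparison of the pools, simulated over 11848 genes, 54 of 100 genes simulated at 2-fold and 97 of 100 simulated at 4-fold were counted, as were 672 of 11648 unchanged genes. Of 200 lists of 20 unchanged genes 7 lay outside, and of 20 lists raised by 0.5 on the log2 scale 20 were found. Smaller shifts, such as the medians of most lists reported below, were not simulated. Lists whose genes vary together were not simulated either.

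Alternatives were median centring, quantile and loess scaling, a pseudocount of 16, no level filter or one at the 75th percentile, the mean over probe sets, leaving out probe sets that can bind several genes, 1.5-fold and 3-fold sizes, 5 or 20 level bins and the mean of a list. Added after seeing the data were agreement of all probe sets of a gene, a filter at the 90th percentile, lists without their farthest member and lists read only through the members' other probe sets. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.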

Results

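Pancreatic RNA of adult male C57BL/6J mice, an inbred laboratory strain, was measured on 2 expression arrays. The mice differed in what their mothers ate in pregnancy, which was either a control diet or a diet deficient in methionine, an essential amino acid and the main source of methyl groups for methylation reactions. After weaning at 3 weeks all of them ate control diet, and their age was 10 weeks, so the comparison asks which pancreatic transcripts differ in adult offspring after a maternal diet low in methionine. The RNA of each group was combined into 1 pool, and each pool was hybridised to 1 array. With n = 1 array per group, neither the spread between mice nor that between arrays could be measured, and all values below are single values without a p-value. As the error of a log2 difference, the robust SD between probe sets of the same gene is given instead, which covers only probe noise within these 2 arrays. Over 5 bins of probe sets from dimmest to brightest, it was 0.78, 0.59, 0.41, 0.28 and 0.18. Each array held 45101 probe sets, with a median intensity of 165 in the control pool and 171 in the methionine-deficient pool.

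Most digestive enzyme genes and the insulin gene Ins2 had close intensities in both pools, at levels near the top of the arrays' range where a difference can be compressed, while immunoglobulin and plasma cell transcripts were lower and the clock output gene Dbp was higher in the methionine-deficient pool. Ighm, the heavy chain of IgM, was 2.32-fold lower in its brightest probe set (log2 difference -1.22, probe-set spread 0.18). Its 5 probe sets past the filter were all lower, with log2 differences from -1.22 to -0.26. Dbp, a transcription factor that follows the circadian clock, was 3.71-fold higher (log2 difference 1.89, probe-set spread 0.28). Genes for chaperones of the endoplasmic reticulum were lower by small amounts, with a median log2 difference of -0.11 and 28 of 36 members lower. Of 11848 genes past the level filter, 459 were at least 2-fold higher and 332 at least 2-fold lower, and 80.6% differed by less than 1.5-fold.

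**Figure D1:**
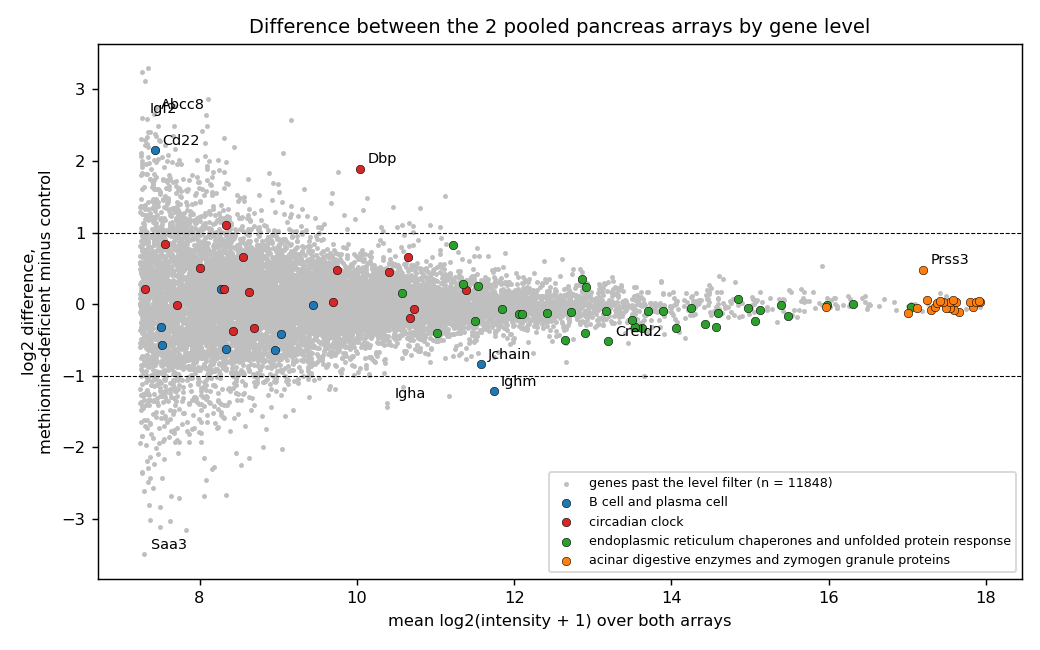
Log2 difference between the pools (methionine-deficient minus control, vertical axis) against the mean log2(intensity + 1) of both arrays (horizontal axis), with 1 point per gene for the 11848 genes past the level filter, dashed lines at 2-fold, and 4 gene lists in colour. Differences of single genes widen toward low levels, the digestive enzymes lie at the bright end close to 0, and Dbp and Ighm lie outside the 2-fold lines at higher levels than most other genes there.

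Acinar cells make digestive enzymes, and 21 of the 22 measured genes for these enzymes and other zymogen granule proteins differed by less than 0.15 on the log2 scale. Carboxypeptidase gene Cpa1 had an intensity of 168872 in the control pool and 170196 in the methionine-deficient pool, and the elastase gene Cela1 had 188258 and 181026. The exception was the trypsinogen gene Prss3, at 127298 and 177568 (log2 difference 0.48, probe-set spread 0.18), whose probe set can bind near-identical trypsinogen transcripts, so the value is uncertain. All members had intensities of at least 62836, near the top of the arrays' range, where a difference can be compressed. Ptf1a, a transcription factor that acinar identity depends on, had a log2 difference of -0.32, and the 10 acinar regulators measured had a median of -0.04.

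Among islet hormone transcripts, Ins2 had an intensity of 93733 in the control pool and 93461 in the methionine-deficient pool, in the same bright range as the enzymes. Iapp, the islet amyloid peptide co-secreted with insulin, differed by 0.04 on the log2 scale in its brightest probe set and by up to 0.38 in its 4 probe sets, and somatostatin (Sst) by -0.07. Glucagon (Gcg) was 1.31-fold higher (log2 difference 0.39, probe-set spread 0.18). The 20 islet hormone and dense-core granule genes had a median log2 difference of -0.01, with 9 higher and 11 lower, while their other probe sets had a median of 0.16 at percentile 90.7, with 4 of 5 higher. Among 18 genes of beta cell identity and glucose sensing, 10 were higher and 8 lower, with a median of 0.10. Their regulator Pdx1 had a log2 difference of 0.60 and the glucose transporter Slc2a2 one of -0.52, each with a probe-set spread of 0.41. Abcc8, the sulphonylurea receptor subunit of the beta cell potassium channel, was 6.30-fold higher, and its 2 probe sets gave log2 differences of 2.66 and 2.29. Its control intensity of 67.3 was below that array's median, where background can set the value.

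The B cell and plasma cell list was the farthest below its random lists. Of its 10 measured members 8 were lower, and its median log2 difference was -0.49, at percentile 0.13 among 10000 random lists matched on level. Jchain, which joins IgM and IgA into polymers, had a log2 difference of -0.84 (probe-set spread 0.18), and Ms4a1, the B cell surface protein CD20, had -0.64 (probe-set spread 0.41). Cd22, another B cell surface protein, went the other way at 2.15 with a probe-set spread of 0.78, from a control intensity of 81.3. Over all immunoglobulin and J chain probe sets past the filter, a set drawn up after values were seen, 17 of 20 were lower with a median of -0.85. Those of constant regions and the J chain were lower in 13 of 13 cases, 6 of them at least 2-fold, with a median of -0.95. This count leaves out a probe set annotated to the kappa locus as a whole (Igk), which was 2.08-fold higher. Igha, the heavy chain of IgA, was also singled out after its values were seen, and its 3 probe sets had log2 differences between -2.66 and -1.14. Immunoglobulin probe sets can bind related segments, so the share of each class is uncertain. The 17 macrophage and other myeloid genes had a median of -0.03, with the complement gene C1qa at 1.01, and the 7 T cell genes had a median of -0.24, at percentile 12.6. The T cell value has no settled direction, since it was 0.047 without its farthest member and 0.16 without a level filter. The B cell list lay inside the range of random lists without a level filter (median -0.02) and by its mean in place of its median (-0.23, percentile 9.19).

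**Figure D2:**
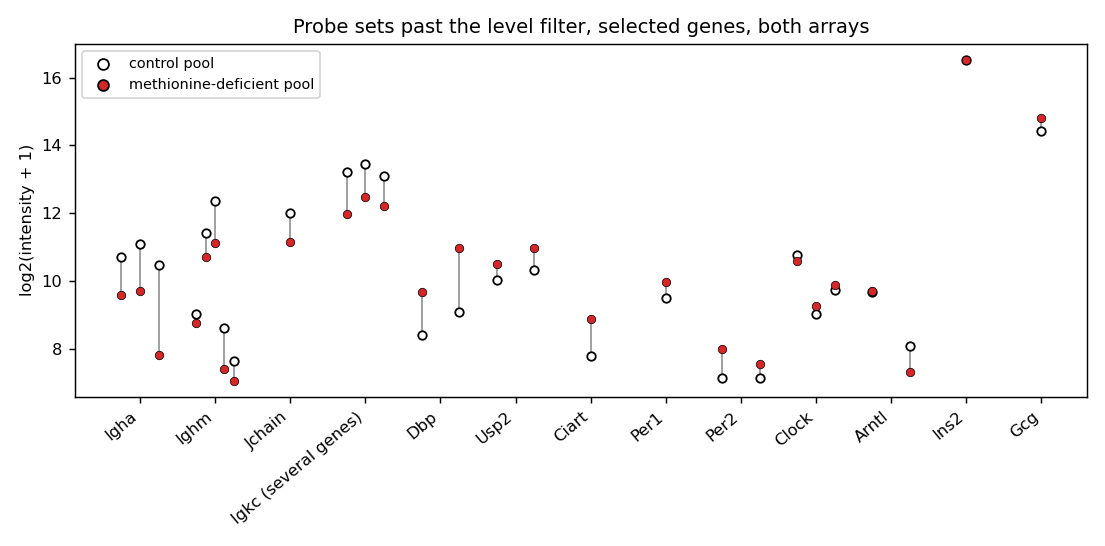
Log2(intensity + 1) of each probe set past the level filter in the control pool (open circles) and the methionine-deficient pool (red circles) for selected immunoglobulin, clock and islet hormone genes, with 1 line per probe set joining its 2 values. Each probe set shown for Igha, Ighm, Jchain and Igkc is lower in the methionine-deficient pool, while a further probe set annotated to the kappa locus (Igk), not drawn, is 2.08-fold higher, both Dbp probe sets are higher, and the values for Ins2 overlap.

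Clock genes were higher in 13 of 18 cases, with a median log2 difference of 0.21 at percentile 95.7, within the central 95% of random lists. The list lay above that range with the 75th percentile level filter (percentile 99.7), with the mean over probe sets (98.2) and by its mean (99.3). Dbp led the list, and its 2 probe sets gave 1.28 and 1.89. Ciart, a repressor within the clock, had a log2 difference of 1.11 (probe-set spread 0.59), the clock-regulated protease Usp2 had 0.66 (probe-set spread 0.18), and the period gene Per2 had 0.84 (probe-set spread 0.78). The glucocorticoid-responsive list, which shares Per1 with the clock list, had a median of 0.19 at percentile 99.8, with 9 of 13 members higher. Its largest difference was that of Errfi1, an inhibitor of EGF receptor signalling, at 0.67. Of the 4 lower members, Cdkn1a had -0.40 and -1.07 in its 2 probe sets. Fkbp5, also lower and named after its values were seen, had -0.11 and -1.34 in its probe sets past the filter. Nr3c1, the glucocorticoid receptor itself, had 0.42 from its brightest probe set but -0.15 as the mean over its probe sets. Over the members' other probe sets alone, the list's median was -0.08, so its direction rests on the brightest probe sets. It lay inside the range with no level filter (percentile 95.3) and with the mean over probe sets (95.2).

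Chaperone and unfolded protein response genes of the endoplasmic reticulum lay at percentile 0.49. Creld2 had a log2 difference of -0.52, the disulfide isomerase gene Pdia3 had -0.51, and the major chaperone gene Hspa5 had -0.23 with all 3 of its probe sets lower, each beside a probe-set spread of 0.18. Ern1, a sensor of unfolded proteins, was higher at 0.82, but its second probe set gave -0.43. The other probe sets of these genes, not used for the median, were lower in 38 of 50 cases, at percentile 0.09. Without probe sets that can bind several genes the list lay just inside the range, at percentile 2.59. The proteasome list had a median of -0.14 at percentile 0.22, with 26 of 35 members lower. Its catalytic subunit gene Psmb5 had -0.43, while Psmd5, which encodes an assembly chaperone, had 0.57 and Psmc2 had 0.49. It lay inside the range by its mean (percentile 4.94), and its other probe sets had a median of -0.01, at percentile 41.6. The ratio of 3' to 5' control probe sets, a sign of RNA quality, was 1.46 in the control pool and 1.76 in the methionine-deficient pool for Actb. For Gapdh it was 0.973 and 1.11. The log2 shifts of 0.27 and 0.19 each rest on a pair of probe sets. The spread of a single bright probe set was 0.18, so probe noise could give such shifts. For Actb the middle probe set was lower than the 5' one (log2 differences -0.26 and -0.16).

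Genes of methyl-group metabolism, which the maternal diet concerns most directly, had list medians between -0.18 and 0.18 from their brightest probe sets. Some single genes differed more. Folate and serine-glycine one-carbon genes had a median log2 difference of 0.18 at percentile 99.4, although only 10 of 18 were higher. Among them Mthfd1, a folate-interconverting enzyme, had 0.65 (probe-set spread 0.18), Fpgs, which retains folate in cells, had 0.67 (probe-set spread 0.28), and Ftcd had 0.94 (probe-set spread 0.59). The list lay inside the range of random lists with the 75th percentile level filter (median 0.065), with the mean over probe sets (0.063, percentile 84.9) and by its mean (percentile 95.9), and the members' other probe sets gave a median of -0.03. In the methionine cycle, transsulfuration and polyamine list 18 of 24 genes were higher, with a median of 0.05 at percentile 91.8, led by Nnmt at 0.81 and by the methionine salvage gene Adi1 at 0.63 with all 3 of its probe sets higher. With each array's median subtracted, the median of this list was -0.0022. Among 12 genes of DNA methylation and demethylation 9 were lower, with a median of -0.18 at percentile 7.73. With the 75th percentile level filter the median was -0.25 at percentile 2.01, outside the range of random lists. The direction turned with the mean over probe sets (median 0.21), by the list's mean (0.066) and over the members' other probe sets, of which 11 of 17 were higher (median 0.29, percentile 95.6). The maintenance methyltransferase gene Dnmt1 had -0.08 from its brightest probe set and 0.57 from its second, and Dnmt3b had -0.21. Dnmt3a had -0.38 from its brightest probe set and 0.24 as the mean over its probe sets. Mbd3, a methyl-CpG-binding domain gene, was 5.63-fold higher from a control intensity of 85.4. Imprinted genes, whose expression depends on DNA methylation, were higher in 9 and lower in 14 of 23 cases with a median of -0.10. Among them Igf2 was 6.05-fold higher in 1 probe set, from a control intensity of 61.7, where background can set the value. Another Igf2 probe set, below the level filter, had 24.4 in the control pool and 44.4 in the methionine-deficient pool. A change in imprinting was not tested. The list of amino acid response genes had a median of -0.03. Its other probe sets were lower in 24 of 30 cases, with a median of -0.11 at percentile 3.68, inside the range. Its member Asns, the asparagine synthetase gene, had intensities of 34028 and 34015. Another response gene, Ddit3, had a log2 difference of 0.39 with a probe-set spread of 0.59.

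**Figure D3:**
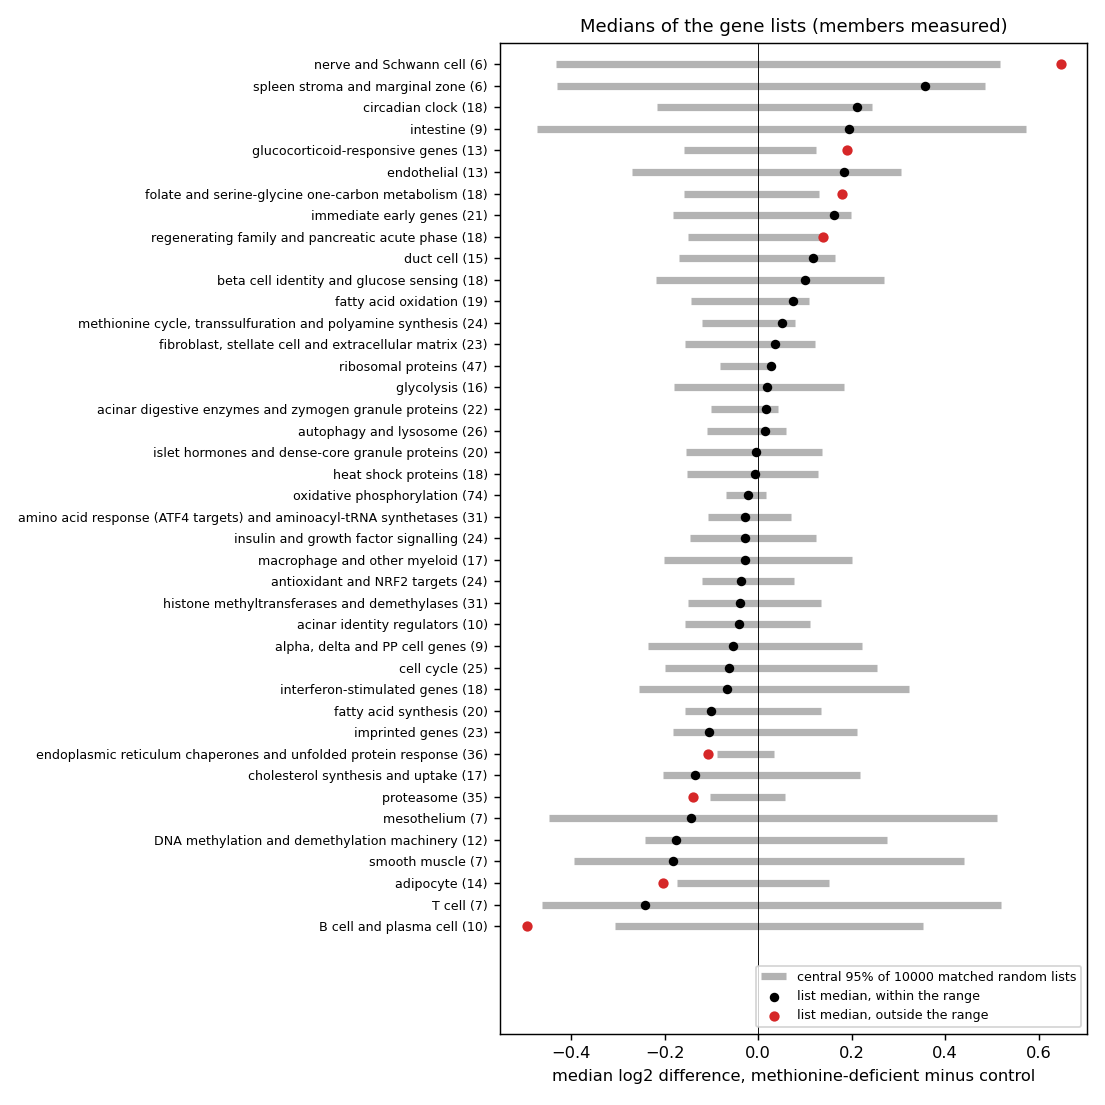
Median log2 difference (methionine-deficient minus control, horizontal axis) of the 41 gene lists with at least 5 measured members, the number measured in parentheses, and as grey bars the central 95% of 10000 random lists of the same size and level. The 8 lists in red lie outside their bars, 4 below and 4 above, and the other 33 lie within.

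Of the 41 lists measured, 8 lay outside the central 95% of their random lists and 33 lay within. By chance 2.05 are expected outside if the members of a list vary independently. Genes of 1 list can vary together and some lists share members, so more could fall outside without an effect of the diet. Beside those above, adipocyte genes were lower in 12 of 14 cases with a median of -0.20 at percentile 1.11, among them the lipid droplet gene Cidec at -1.59 and the gluconeogenic enzyme gene Pck1 at -1.56, whose second probe set gave 0.08. Over their other probe sets, 6 of 10 lower, the median was -0.12 at percentile 17.5, inside the range. The regenerating family and acute phase list had a median of 0.14 at percentile 97.8. It lay inside the range with quantile scaling (percentile 96.8), 5 level bins (96.5), no level filter (94.4) and by its mean (84.2), and over its other probe sets (median 0.023, percentile 63.7). Its antimicrobial lectin gene Reg3b was 1.44-fold higher with both of its probe sets higher, while Reg1 and Reg2, which are as bright as the digestive enzymes and so open to the same compression, had log2 differences of -0.07 and 0.16. The acute phase genes Lbp and Saa3 lay at 3.11 and -3.50. Nerve and Schwann cell genes were higher in 5 of 6 cases with a median of 0.65 at percentile 99.0, led by Ngfr at 1.76. The list lay inside the range without its farthest member (median 0.25, percentile 83.2), with no level filter (percentile 87.1) and with the mean over probe sets (90.9), and the median over other probe sets was 0.07. Percentiles describe these 2 arrays and are not a test of the diet.

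The largest differences of single genes were at low levels. Of the 15 largest higher and the 15 largest lower genes, headed by Spout1 (log2 difference 3.30) and Saa3 (-3.50), all 30 had their dimmer value below that array's median intensity and 29 rested on a single probe set. Adcyap1, the gene of a neuropeptide, was in the lower set at -3.12. Among the 2962 dimmest genes past the filter 339 were at least 2-fold higher and 234 lower, and among the 2962 brightest 9 and 4. Where a gene had a second probe set past the filter, 40 of 72 higher and 31 of 57 lower genes had it in the same direction, with 50% expected by chance. Genes with 2 or more probe sets, all at least 2-fold different in the same direction, numbered 5 higher and 3 lower. Named after their values were seen, they were Abcc8, Dbp, Sema6c, Vsir and a transcript with no gene name on the higher side, and Igha, Capn8 and Csgalnact1 on the lower side. How many such genes probe noise alone would give was not computed, so their number is not shown to exceed it. Simulated unchanged genes with the same probe noise passed 2-fold in 5.77% of cases, against 6.68% of the measured genes.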

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

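Of the tests in this part, the test on the chaperone and proteasome genes together was set before its values were seen. The time-of-day test was also written beforehand, but only its genes that peak with Dbp were unseen. Its opposite-phase genes belong to the clock list and had been looked at. The other tests were chosen after the result was seen. The poly-A spike-in controls, bacterial transcripts that can be added to RNA before labelling, stood out as a signal outside the main measurement. They had a median log2 difference of 0.1816 (methionine-deficient minus control) and 23 of 24 probe sets higher, but several probe sets read the same transcript. The hybridization controls had a median of -0.019 with 8 of 18 higher. The poly-A offset was close in size to the folate and glucocorticoid medians (0.18 and 0.19), and scaling to these controls was not tried. A common rescaling moves a list and its random lists alike, so it could change these medians but not the percentiles. With each array's median subtracted, the percentiles of these lists stayed at 99.4 and 99.8.

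Immunoglobulin and plasma cell transcripts were lower in the methionine-deficient pool. Noise of single probe sets was argued against by the list's 5 other probe sets, all lower, with their median at percentile 1.05 of random sets, although most of them belong to Ighm. Fewer leukocytes of all kinds was argued against by the macrophage and other myeloid median of -0.029. A lymph node or other lymphoid tissue carried along with the control pancreas may account for the pattern and was not tested as such, and the T cell median of -0.24 turned to 0.047 without its farthest member, while all 6 spleen stroma and marginal zone genes were higher (median 0.36, inside the range of random lists). Fewer plasma cells in pancreas after a maternal diet low in methionine, or 1 mouse with many in the control pool, stay open as hypotheses.

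Dbp and some other clock genes had higher values in the methionine-deficient pool, although the clock list as a whole lay within its random lists. The list's other probe sets had a median at percentile 92.6, which leaves noise of single probe sets open, although both Dbp probe sets were more than 2-fold higher. A difference in the time of day of collection may account for this pattern. It predicted higher values of genes that peak together with Dbp. For 3 of these, not looked at before, the median log2 difference was 0.022 with 2 higher, Wee1 at 0.78 and Lonrf3 at only 0.022. Tspan4 was lower at -0.74, and Por, also named beforehand, gave no value past the level filter. For 4 genes of opposite phase, members of the clock list already looked at, the median was -0.10. Time of day and maternal diet cannot be told apart here, because collection times are not given in the sources used here and the in-phase genes were few.

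Chaperone genes of the endoplasmic reticulum and proteasome genes were lower in the methionine-deficient pool. The other probe sets of both lists together had a median at percentile 0.05, which argued against noise of single probe sets, but the lists differed when separated afterwards. The chaperone genes stood at percentile 0.09, while the proteasome genes stood at 41.6, as noise of single probe sets predicted, so the proteasome result may be noise. More degraded RNA in the methionine-deficient pool may account for the chaperone result, since the 3' minus 5' log2 shift of the Actb and Gapdh controls was 0.23 on average. A shift of this size is not clearly beyond probe noise, and how far each probe set lies from the 3' end was not analysed here. An effect of the maternal diet stays open as an untested hypothesis.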

How the results depend on the processing

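Settings said here to be added were chosen after seeing the data; no paired analysis was possible because each group is 1 pooled sample on 1 array, and for the same reason no replicate could be left out. The counts of genes at least 2-fold higher and lower (459 and 332) were 2322 and 2003 with no level filter, 52 and 38 with the 75th percentile filter, 1236 and 1066 at 1.5-fold, 129 and 86 at 3-fold, and, added, 8 and 4 with the 90th percentile filter and 5 and 3 where every probe set had to differ 2-fold. Without a level filter 4 lists lay outside. With each array's median subtracted, the medians of the chaperone and proteasome lists were -0.16 and -0.19. With no level filter, those of the B cell, glucocorticoid and nerve lists were -0.017, 0.11 and 0.31, and with the 75th percentile filter that of the folate list was 0.065. As the mean over probe sets, the folate, glucocorticoid and nerve medians were 0.063, 0.11 and 0.35. Without its farthest member, added, the nerve median was 0.25. Over other probe sets only, added, the folate and glucocorticoid medians reversed to -0.031 and -0.082, and those of the B cell, adipocyte, nerve, proteasome and regenerating lists were -0.71, -0.12, 0.071, -0.012 and 0.023. The cause was not tested, except that fewer or more genes pass a changed filter or size. Low signal over background limits the dim genes. The share of higher genes among those 2-fold different was 58.0%, and 51.2% to 58.8% under the scalings, filters and probe-set choices planned beforehand. Of 12 other settings, not counting other probe sets alone, adipocyte genes lay outside in 12, and chaperone and proteasome genes in 11 each. B cell and glucocorticoid genes lay outside in 10 each, folate genes in 9, regenerating genes in 8, and nerve genes in 8 of the 11 that left enough members. These counts include the setting with each array's median subtracted, which could not change any percentile because it moves a list and its random lists alike. Over other probe sets alone, the B cell and chaperone lists stayed outside on the same side and the other 6 did not. For the B cell list this rests on 5 probe sets, most of them of Ighm, so it says little on the other members. Of the lists inside at first, the clock and ribosomal lists lay outside in 3 settings each, and the DNA methylation, cholesterol, duct, fatty acid oxidation, immediate early and spleen stroma lists in 1 each. Single genes named kept their value within the probe-set spread in all but 13 of 447 cases. Changed filters leave a gene's brightest probe set as its value, so little movement was possible in those settings. The count says nothing on agreement between probe sets, which had a Pearson r of 0.028 across genes.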

Other observations

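The observations on other probe sets in this part were chosen after the result was seen. They were picked from all lists with enough other probe sets, among which some would lie outside the range by chance. Immediate early genes, which respond within minutes to handling or stimulation, were higher in 14 of 21 cases with a median log2 difference of 0.16 at percentile 94.6, and their other probe sets were higher in 9 of 11 cases at percentile 99.97. The members went both ways: Egr1 had the largest difference and was lower at -1.41, while the stress-induced Atf3 was higher at 1.24, each with a probe-set spread of 0.59. Methionine cycle genes also kept their direction over other probe sets, with 10 of 13 higher at percentile 98.6. From the brightest probe sets, that list's median was -0.0022 with each array's median subtracted. Cell cycle genes were lower in 16 of 25 cases at percentile 22.4, with 15 of 19 other probe sets lower at percentile 0.445. Cholesterol synthesis genes went opposite ways, with a median of -0.13 in their brightest probe sets and 0.33 in the others.

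In the main setting, the remaining cell types and pathways lay inside the range of random lists, and many of these small medians have no settled direction. The duct median, for example, was -0.0081 with no level filter and -0.11 over other probe sets, and the interferon median was 0.33 with the 75th percentile filter. The duct list lay above the range without its farthest member (percentile 97.7), fatty acid oxidation with the mean over probe sets (99.6) and spleen stroma by its mean (98.1). Duct cell genes had a median of 0.12, endothelial genes 0.18, fibroblast and stellate cell genes 0.04, smooth muscle genes -0.18, mesothelial genes -0.14, intestinal genes 0.19, and genes of alpha, delta and PP cells -0.05. All 6 genes of spleen stroma and marginal zone were higher, with a median of 0.36 at percentile 92.3. Ribosomal protein genes had a median of 0.03 at percentile 96.8, or -0.026 with each array's median subtracted, oxidative phosphorylation genes -0.02, glycolysis genes 0.02, fatty acid oxidation genes 0.07 and fatty acid synthesis genes -0.10. Autophagy and lysosome genes had a median of 0.02, heat shock genes -0.01, antioxidant genes -0.04, insulin and growth factor signalling genes -0.03, interferon-stimulated genes -0.07, and histone methyltransferase and demethylase genes -0.04.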
